A study of Drosophila melanogaster with 78 samples.

How the data were processed

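RNA from whole Drosophila melanogaster embryos at stage 15 was measured on 78 Affymetrix arrays of the early genome-wide fly design. Per the labels, RNA was purified on QIAGEN columns, 6 ug of total RNA was labelled with biotin, and the arrays fall into 18 groups of 4 or 5. The deposited values are intensities in the unit intensity, on a linear scale, which the submitters' processing notes describe as made with RMA; the version is not given in the sources used here. The values had been planned for as log2 values, and since the table holds linear intensities, log2 was taken before any step. The median intensity per array lay between 811.1 and 857.7, and no 2 arrays were identical. The number of arrays per group limits the precision.

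The table held 14010 probe sets, of which 44 Affymetrix controls were left out, so that 13966 were tested. A single gene name applied to 12443 probe sets, several names to 327 and none to 1196; the names cover 10844 genes. Names were brought to the RefSeq gene table of the Release 6 plus ISO1 MT assembly through Entrez identifiers for 12394 probe sets, and 49 kept the name of the platform annotation. For the 1209 genes with several probe sets, the probe set with the highest mean over all arrays stands for the gene.

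A model with 18 group means was fitted to all 78 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes), with 60 residual degrees of freedom. It gave 17 contrasts against WT and 12 between related groups. Tests were two-sided, with Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05. A moderated F test covered the 17 contrasts against WT. Changes are given as log2 ± SE of the fit, fold changes beside them, and group levels as mean ± SD of the arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

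For gene groups, 17 lists with 402 genes were fixed before the data were examined, as were the comparisons, the tests, the rule for named genes and the settings to be varied. Of the list genes, 292 were measured. The lists were axon guidance ligands and receptors, axon guidance signalling, axonal and neural cell adhesion, CNS midline cells, differentiated neurons, neural precursors, glia, muscle, cuticle and chitin, ecdysone synthesis and response, early embryo patterning, cell cycle, heat shock, antimicrobial peptides, hemocytes and basement membrane, fat body and midgut, and egg chamber and maternal. Each list was tested against all other named genes with camera in limma, with a preset correlation between genes of 0.01 and adjustment over all 289 tests of list and comparison. The same tests were run with an estimated correlation. Whole embryos hold every tissue these lists describe.

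The rule for named genes took axon guidance genes that the labels name or that belong to the same receptor system (sli, robo1, comm, comm2, fra, unc-5 and NetB) in every group. It added the 10 highest and 10 lowest changes past the threshold in slit, robo, robo2 and comm against WT and in slit and robo against comm, and the 5 highest and 5 lowest in the other comparisons. It also took 10 genes called the same way in most comparisons and up to 4 members per list. Some other genes of the receptor system were not analysed here. The text names these genes in order of rank.

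For slit, robo and comm, the share of genes with the same direction in the /WT group was taken with the WT arrays split, replicates 1 to 3 for the calls and replicates 4 and 5 for the /WT group, and compared with simulated unchanged groups. The labels conflict on the replicates: the titles call them biological and the descriptions technical, and the design text gives other replicate numbers. The p-values may therefore measure technical spread only. The labels do not expand FRM, UC, UC2x, UR, UR2, URyf, URyf.mef or robo12, and these names are used as given. A group named with /WT was read as carrying 1 dose of the mutation.

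The fit was tested on simulated data in slit against WT. A planted step of 0.2 on the log2 scale was recovered in 23.9% of the changed probe sets, a step of 0.5 in 97%, and 8 of 155 calls were false (5.16%). The simulated noise was independent between probe sets, so it held no deviation of a whole array. When the real arrays' deviations from their group means were reshuffled with no group effect, slit against WT had calls in 5 of 100 draws. The highest of these draws had 2652 calls, so the share of false calls above does not cover such deviations.

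The settings varied by that plan were quantile normalization, leaving out dim probe sets (below percentile 40), fitting only the compared groups, a replicate block, array weights, leaving out each array in turn, comparing with the mean of the other groups in place of WT, an estimated correlation for the lists, and splitting the WT arrays the other way. After the data were seen, array SD as a covariate and a fit without arrays that stand apart were added. Arrays stand apart when their SD lies over 0.05 from the group mean or their GAPDH 3'-to-5' difference is above 2.5, which holds for 6 arrays. No array was left out otherwise.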

Results

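Gene expression was measured in stage 15 embryos of 18 genotypes. The WT, UC2x, UNC5, URyf, URyf.mef and slit.robo groups held 5 arrays each. FRM, UC, UR, UR2, comm, comm/WT, robo, robo/WT, robo12, robo2, slit and slit/WT held 4 each. The slit gene encodes the midline repellent, robo1 its receptor, and comm a protein that keeps the receptor off crossing axons. In 78 of 78 arrays, the median correlation with the own group lay above the median with all other groups pooled. Single other groups were not compared. The median correlation was 0.9969 within groups and 0.9881 between groups. Differences within groups made up 26.1% of the variance, and 30.3% of that lay on a single axis, whose correlation with the array SD was -0.955 (Spearman -0.934, both across arrays after removing group means). The SD of log2 intensities was 1.711 ± 0.035 (SD, n = 5) in WT and above that in most other groups, up to 1.805 ± 0.015 in URyf.mef. The 3'-to-5' difference of the GAPDH control was 1.71 in WT, 1.92 in comm, 2.19 in robo/WT and 2.28 in comm/WT. The comm/WT arrays were uneven, with 2.8 and 2.75 in replicates 1 and 2 and 1.81 and 1.78 in replicates 3 and 4.

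**Figure D1:**
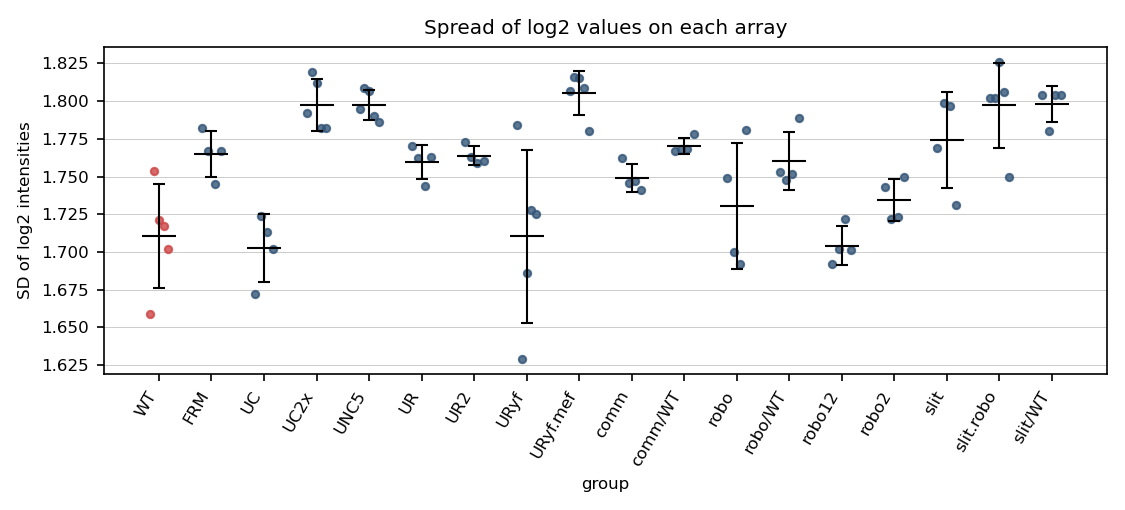
SD of the log2 intensities on each array (y axis, log2 units) by group (x axis), with bars for mean and SD of the group. WT (red) averages 1.711, while UC2x, UNC5, URyf.mef, slit.robo and slit/WT average above 1.79.

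The genes sli, robo1, comm and unc-5 were examined as a check of the groups named for them, and the robo2 group was not checked in this way. The transcript of unc-5, a netrin receptor for repulsion, rose in UNC5 by 1.81 ± 0.06 (3.5-fold, adjusted p = 6.5e-39), to 13.26 ± 0.03 (SD, n = 5) from 11.45 ± 0.13 in WT. The other probe sets of unc-5 rose by 0.57 ± 0.07 and 2.96 ± 0.13. The transcript of comm rose in UC by 0.47 ± 0.05 (1.39-fold, adjusted p = 3.6e-12) and in UC2x by 0.87 (1.82-fold, adjusted p = 2e-25), and UC2x exceeded UC by 0.4 (1.32-fold, adjusted p = 5.4e-10). The transcript of robo1 rose in FRM by 0.95 ± 0.07 (1.93-fold), in UR by 1.32 (2.5-fold), in URyf by 2.37 (5.18-fold) and in URyf.mef by 3.2 (9.17-fold), with every array above every WT array. In UR2 the robo1 change was 0.15 (adjusted p = 0.079), and it passed with array weights (0.17, adjusted p = 0.01), with array SD as covariate (0.19, adjusted p = 0.042), without arrays that stand apart (0.21, adjusted p = 0.0066) and without WT replicate 1 (0.21, adjusted p = 0.02). In the groups named for loss of a gene, the changes were small. The sli transcript was 9.42 ± 0.21 (SD, n = 4) in slit and 9.68 ± 0.33 in WT, a change of -0.26 ± 0.1 (adjusted p = 0.033) that was lost after quantile normalization (adjusted p = 0.059), with array SD as covariate (adjusted p = 0.23) and without arrays that stand apart (adjusted p = 0.17). In slit/WT sli rose by 0.46 (1.38-fold, adjusted p = 9.3e-05), so slit lay below slit/WT by a log2 change of -0.72 ± 0.11 (1.65-fold, adjusted p = 4.4e-07). The comm transcript fell by 0.25 in comm (1.19-fold, adjusted p = 6.4e-05) and by 0.24 in comm/WT (1.18-fold, adjusted p = 7.2e-05). The robo1 change in robo was -0.19 with an adjusted p = 0.05 at the threshold, and -0.03 (adjusted p = 0.84) without arrays that stand apart. In robo/WT robo1 fell by 0.25 (adjusted p = 0.0021), in robo12 by 0.21 (adjusted p = 0.028, and 0.055 after quantile normalization), and in slit.robo its change was -0.02. Of the genes not named in the labels, comm2, a relative of comm, fell in robo by 0.31 ± 0.06 (adjusted p = 4.2e-05). The netrin receptor gene fra rose in comm/WT by 0.55, in robo/WT by 0.48 and in slit/WT by 0.58, and these 3 calls were lost with array SD as covariate (adjusted p = 0.093, 0.11 and 0.4), that in comm/WT also without arrays that stand apart (0.05, adjusted p = 0.78) and that in robo/WT without WT replicate 1 (0.27, adjusted p = 0.063). The alleles are not in the labels, and a probe set outside a deleted part, or a mutation that leaves the transcript, would not change, so these small values check nothing about the loss groups.

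**Figure D2:**
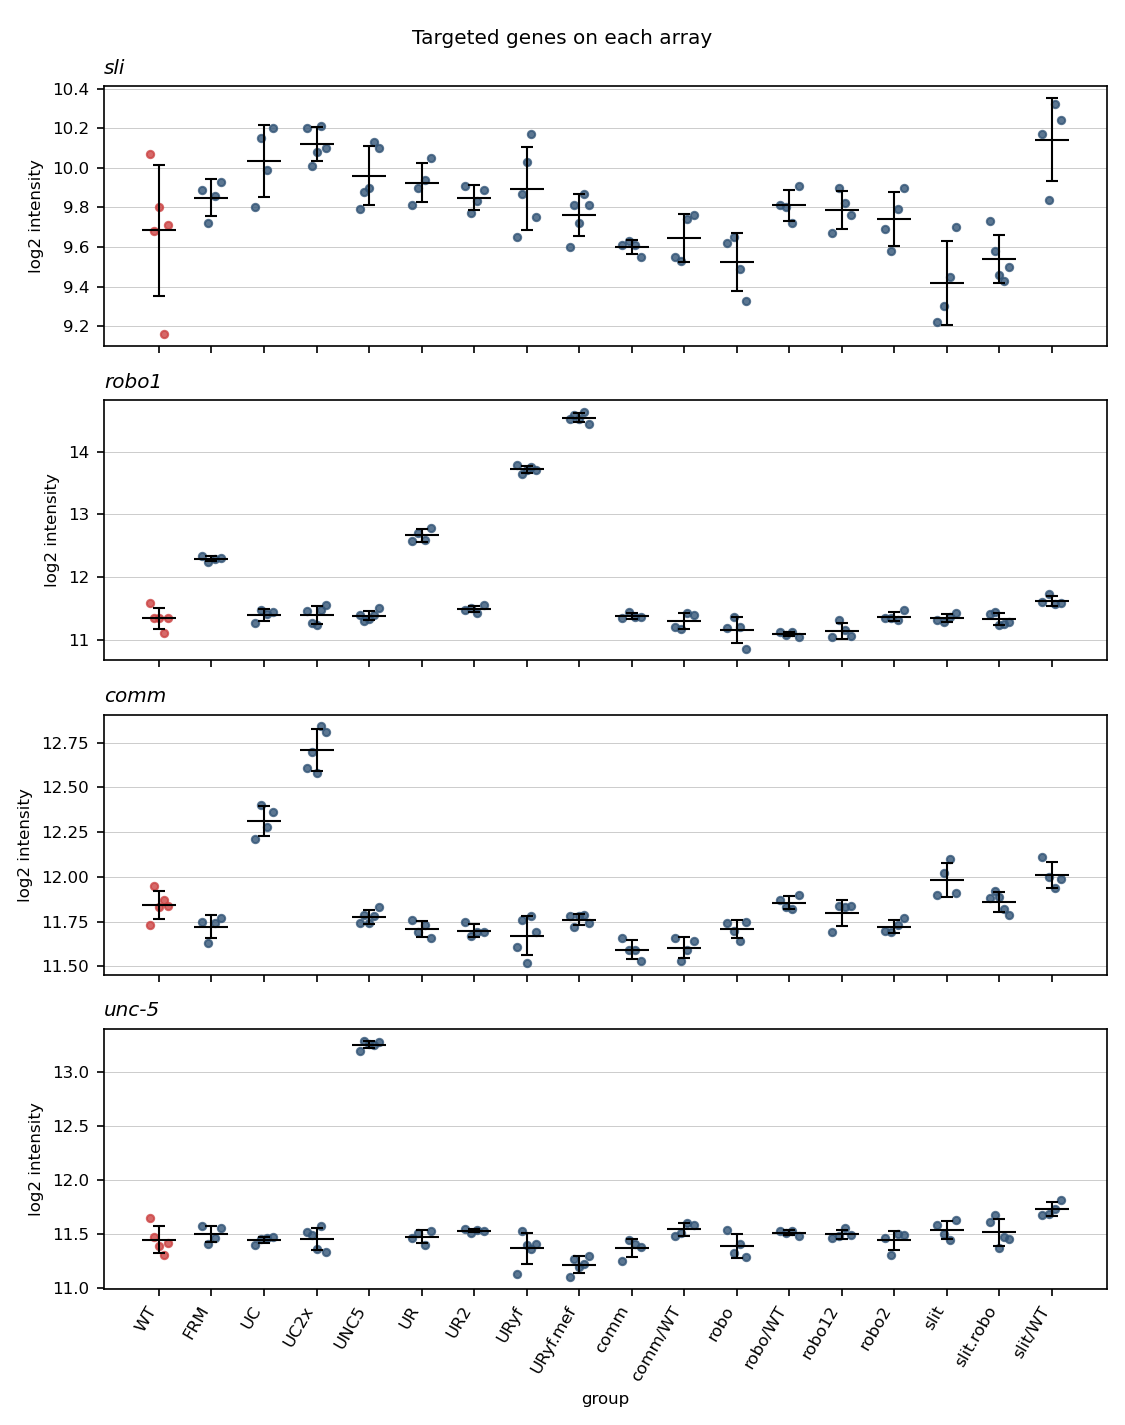
Log2 intensity of sli, robo1, comm and unc-5 (y axes) on each array by group (x axis), with bars for mean and SD of the group and WT in red. The unc-5 transcript averages 13.26 in UNC5, comm 12.71 in UC2x, and robo1 14.54 in URyf.mef.

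Across the whole design, 13578 of 13966 probe sets (97.2%) differed among the groups by the F test. Against WT, NetB, a secreted guidance ligand made at the midline, rose in 17 of 17 groups, from 0.56 in UC (adjusted p = 1.4e-05) to 1.44 ± 0.1 in slit (2.71-fold, adjusted p = 8.7e-19), though UC, UC2x, URyf, comm/WT, robo/WT and robo12 lay below the mean of the other groups. In URyf the NetB arrays overlapped WT, and the call was lost with only the compared groups (0.57, adjusted p = 0.23). Other genes called higher in 17 of 17 groups were Cht6, a chitinase (median 1.58, range 0.75 to 2), Mp, a basement membrane collagen (median 1.38, range 0.74 to 1.88), Cbp53E, a calcium buffer of neurons (median 1.07, range 0.46 to 1.65), and MtnA, a metallothionein (median 0.9, range 0.29 to 1.21). Pepck1, an enzyme of gluconeogenesis, had a median of 0.82 and TwdlQ, a cuticle protein, of 0.76. In total 124 probe sets were called higher and 10 lower in all 17 groups. Lower calls outnumbered higher ones in every group, but without dim probe sets higher calls were the majority in 9 of 17, by at most 55% (UR2, from 44%). In slit the share called higher went from 39.6 to 51.1%, and in UC it went from 44.7 to 43.3%. After quantile normalization higher calls were the majority in URyf (52.2%) and robo (50.7%). All 17 comparisons share the WT arrays, which alone makes overlaps. Simulated unchanged groups gave 0 in all 17, and independent lists of these sizes would give 1.5e-10 and 2.5e-08. Neither value measures how unlikely the overlap is. The simulated groups had few calls to overlap, with no probe set called higher in more than 6 comparisons. Independent lists leave out the shared WT arrays. With WT replicates 1 to 3 against 8 groups and 4 and 5 against the other 9, 73 and 4 were called in all, and 60 and 3 the other way round.

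**Figure D3:**
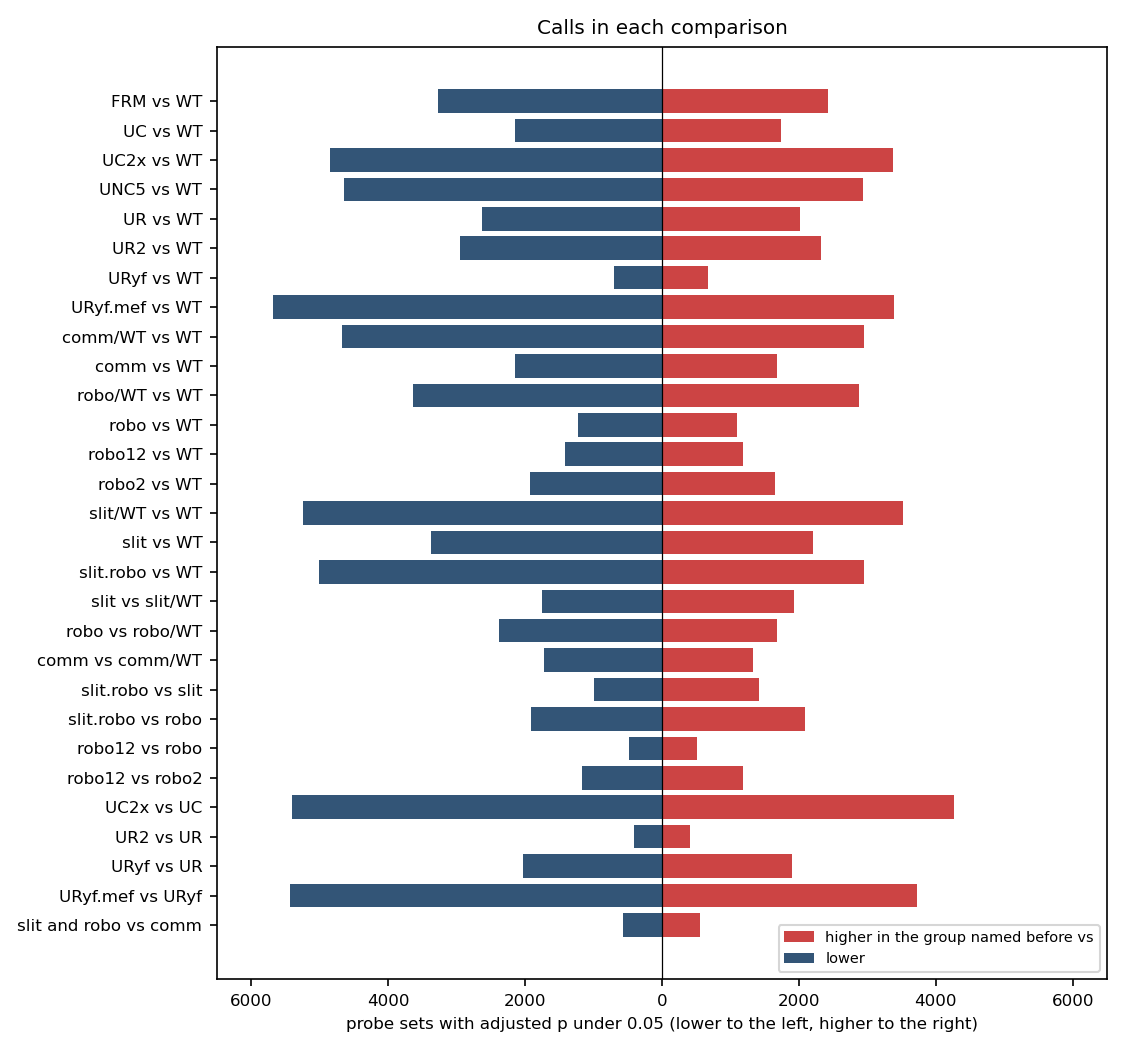
Number of probe sets (x axis) called higher (red, right) and lower (blue, left) in each comparison (y axis) at an adjusted p under 0.05. Counts against WT run from 666 higher and 700 lower in URyf to 3396 higher and 5686 lower in URyf.mef.

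Embryos of the slit group, which lack or reduce the midline repellent by their name, had higher stress chaperones and neural adhesion molecules than WT. The heat shock list rose, with 5 of its 7 measured genes higher and 0 lower (median 0.8, adjusted p = 2.4e-10, and 5 higher adjusted over the list alone). Its small chaperone Hsp26 rose by 2.61 ± 0.15 (6.1-fold, adjusted p = 9.9e-24, n = 4 and 5), Hsp68 by 2.29 ± 0.18 (4.89-fold, adjusted p = 2.1e-17), and the cochaperone DnaJ-1 by 1.31. The axonal and neural cell adhesion list rose, with 16 genes higher, 0 lower and 2 not passing (median 0.44, adjusted p = 4.9e-10, and 16 higher adjusted over the list alone), among them CadN, a neural cadherin (1.16), and Con, an adhesion protein of motor axons and muscles (1.1). Guidance ligands and receptors were higher for 9 genes and lower for 2, with 14 not passing (adjusted p = 0.00046, and 9 and 2 adjusted over the list alone), and the heparan sulfate proteoglycan Sdc rose by 0.83. Over all groups, 1 of the 12 calls of this guidance list was kept without dim probe sets. Ecdysone genes were higher for 9 and lower for 2, with 8 not passing (adjusted p = 0.005, and 9 and 3 adjusted over the list alone), including the nuclear receptor Hr4 (0.61). The egg chamber and maternal list fell, with 9 lower, 0 higher and 6 not passing (median -0.17, adjusted p = 0.03, but adjusted p = 0.39 with an estimated correlation). Its examples were bcd, the anterior determinant (-0.4), and Yp2, a yolk protein (-0.24). Muscle genes were higher for 8 and lower for 2 (adjusted p = 0.0085, but adjusted p = 0.14 with an estimated correlation). Among single genes CG11825 had the highest change, 3.55 ± 0.12 (11.7-fold, adjusted p = 2.9e-37), followed after the chaperones by the zinc transporter ZnT35C (1.63 ± 0.09, 3.1-fold), the cytochrome P450 Cyp6a13 (1.55) and the decapping enzyme DCP2 (1.54). CG18585 (1.53), Hrb27C, an RNA-binding protein (1.46), pst (1.46) and aqz (1.46) completed the highest 10. Uhg1, a host transcript of small nucleolar RNAs, fell most (-2.09 ± 0.14, 4.25-fold, adjusted p = 5.7e-20), then the lysosomal protease cathD (-1.47 ± 0.09, 2.78-fold), CG18367 (-1.08) and the mucin Muc55B (-1.05). Jon65Aiii, a digestive protease (-0.96), BomS2, an immune-induced peptide (-0.96), and Fmo-1, a monooxygenase (-0.93), were also among the lowest. The midgut protease Jon99Fi fell by 0.98 with arrays that overlapped WT (adjusted p = 0.0071). That call was lost with array SD as covariate (adjusted p = 0.18), with only the compared groups (adjusted p = 0.28), and without WT replicate 1 or all arrays that stand apart, where the change was -0.25 (adjusted p = 0.18 and 0.064). In total 2210 probe sets were called higher and 3376 lower, with 65 and 7 of them changed at least 2-fold. The array SD was 1.774 in slit, and with it as covariate 7 of the 11 called lists were kept, muscle (adjusted p = 0.24) and egg chamber (adjusted p = 0.94) not among them, and 3154 probe sets were called.

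Embryos of the robo group, named for the Slit receptor, had higher heat shock genes and lower cell cycle genes than WT. The cell cycle list fell, with 11 of 21 lower and 0 higher (median -0.25, adjusted p = 1.4e-05, and 12 lower adjusted over the list alone). The mitotic cyclins CycB3 (-1.1) and CycB (-0.61) were among them. Heat shock genes were higher for 5 of 7 (median 0.31, adjusted p = 2.1e-06, and 5 adjusted over the list alone), with Hsp26 at 1.18, Hsp68 at 1.15 and DnaJ-1 at 1.03. Differentiated neuron genes were higher for 4 and lower for 1, with 18 not passing (adjusted p = 0.019, and 4 and 1 adjusted over the list alone), with dopa decarboxylase Ddc at 0.74. Cuticle genes were higher for 10 and lower for 2, with 13 not passing (adjusted p = 0.00028, and 11 and 2 adjusted over the list alone, but adjusted p = 0.079 with an estimated correlation). Muscle genes were higher for 7 and lower for 0 (adjusted p = 0.0015, and 7 adjusted over the list alone, but adjusted p = 0.072 with an estimated correlation), with the troponin T gene up at 0.66. CG11825 rose most (3.49 ± 0.12, 11.2-fold, adjusted p = 7.9e-37), then udd, a factor for ribosomal RNA transcription (2.28 ± 0.09, 4.84-fold), the cuticle protein Cpr67Fa2 (1.77 ± 0.18, 3.4-fold), CG15615 (1.72), the chitinase Cht6 (1.58) and Cbp53E (1.51). Uhg1 fell most (-2 ± 0.14, 4.01-fold, adjusted p = 2.9e-19), then ImpL1, an ecdysone-inducible gene of late embryonic epidermis (-1.99 ± 0.12, 3.96-fold), CG12920 (-1.57), CG9184 (-1.48), CG14960 (-1.46), CG14110 (-1.43), CG6026 (-1.39), CG7173 (-1.33), CG3108 (-1.28) and neo, a gene of epidermal denticles (-1.24). ImpE1 and ImpE2, named like ImpL1 for their response to ecdysone, fell by 0.67 and 0.84. In total 1091 probe sets were called higher and 1232 lower, with 50 and 26 changed at least 2-fold. The actin 3'-to-5' difference was 1.24 in robo, each array above every WT array. With only the robo and WT arrays in the fit 709 were called, and other splits of these arrays called up to 4202.

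Embryos of the robo2 group had higher cuticle and neuron genes and lower cell cycle genes than WT. The cuticle list rose, with 16 of 25 higher and 2 lower (median 0.35, adjusted p = 5.1e-09, and 16 and 2 adjusted over the list alone), including the larval cuticle protein Lcp65Af (1.3). Cuticle proteins outside the list rose too, with Cpr67Fa2 at 2.56 ± 0.18 (5.89-fold, adjusted p = 3.7e-20) and TwdlQ at 1.67. Neuron genes were higher for 9 and lower for 1, with 13 not passing (adjusted p = 0.00033, and 10 and 1 adjusted over the list alone), with Ddc at 0.94 and the GABA-synthesis enzyme Gad1 at 0.5, while tyrosine hydroxylase ple fell by 0.44. Cell cycle genes were lower for 12 and higher for 0, with 9 not passing (median -0.21, adjusted p = 7.8e-05, and 14 lower adjusted over the list alone), with CycB3 at -0.88. The heat shock list had 3 higher and 0 lower (adjusted p = 0.0087, but adjusted p = 0.088 with an estimated correlation), with Hsp26 at 1.09. CG11825 rose by 2.78 ± 0.12 (6.87-fold, adjusted p = 7.9e-31), CG14327 by 1.85, udd by 1.82, Mp by 1.8, CG15615 by 1.79, Cht6 by 1.72 and Drsl5, a drosomycin-like peptide, by 1.56. The lowest were ImpL1 (-2.79 ± 0.12, 6.92-fold, adjusted p = 5.3e-30), the serine protease gene flz (-2.12 ± 0.12, 4.36-fold, adjusted p = 1.7e-24), CG7173 (-1.98), Uhg1 (-1.86), CG12920 and CG14960 (both -1.78), CG3108 (-1.72), CG6026 (-1.66), CG12009 (-1.54) and dsx-c73A (-1.53). Ama, a secreted adhesion protein, fell by 0.96, and Pxn, a peroxidase of hemocytes, by 0.9. In total 1648 probe sets were called higher and 1930 lower, with 116 and 49 changed at least 2-fold. With only the compared groups in the fit 1944 were called.

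Embryos of the comm group had higher muscle, midline and heat shock genes than WT, by lists of which a minority of members passed. The muscle list rose, with 9 higher and 0 lower (median 0.16, adjusted p = 0.00026, and 11 and 1 adjusted over the list alone), with the troponin gene up at 0.74. Midline genes were higher for 3 and lower for 0, with 9 not passing (adjusted p = 0.0092, and 4 higher adjusted over the list alone). Adhesion genes were higher for 7 and lower for 1, with 10 not passing (adjusted p = 0.0022, and 8 and 1 adjusted over the list alone, but adjusted p = 0.18 with an estimated correlation), including CadN (1.3) and Con (1.09). Heat shock genes were higher for 3 and lower for 0 (adjusted p = 0.0027, and 3 adjusted over the list alone), with Hsp26 at 0.76 and DnaJ-1 at 0.65. Antimicrobial peptides were lower for 3 and higher for 0, with 7 not passing (adjusted p = 0.044, but adjusted p = 0.29 with an estimated correlation), and Drsl5 fell most of all genes (-1.84 ± 0.11, 3.58-fold, adjusted p = 1.6e-23). Single genes that rose were CG11825 (2.51 ± 0.12, 5.71-fold, adjusted p = 5.3e-28), Cpr67Fa2 (2.24 ± 0.18, 4.71-fold), Cht6 (1.95), Cbp53E (1.57 ± 0.09, 2.97-fold), DCP2 (1.57), Mp (1.56), the chromatin regulator trx (1.51), TwdlQ (1.49) and the synaptic adhesion gene Nrx-1 (1.46 ± 0.11, 2.75-fold, adjusted p = 7.4e-18). After Drsl5, the lowest were CG7173 (-1.58), ImpL1 (-1.45 ± 0.12, 2.73-fold), CG12920 and CG14960 (both -1.42), CG9184 (-1.41), CG6026 (-1.34), dsx-c73A (-1.18), the sulfotransferase St1 (-1.14) and the serpin Spn43Aa (-1.11). In total 1685 probe sets were called higher and 2144 lower, with 66 and 16 changed at least 2-fold. The GAPDH and actin 3'-to-5' differences were 1.92 and 1.46 in comm, above every WT array, and with array SD as covariate 6 of the 12 called lists were kept, adhesion (adjusted p = 0.11) and immune peptides (adjusted p = 0.29) not among them. The count was 2454 without WT replicate 1 and 1715 with only the compared groups in the fit.

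By their names, slit and robo against comm sets mutants of a repellent and its receptor against a mutant of that receptor's inhibitor. The comm transcript itself was higher by 0.26 (adjusted p = 2.3e-05). Drsl5 differed most, by 2.74 ± 0.1 (6.69-fold, adjusted p = 1.1e-35), having risen in slit (1.02) and robo (0.78) and fallen in comm. CG34166 (1.42), pst (1.38), udd (1.16 ± 0.08, 2.23-fold), Hsp26 (1.14 ± 0.14, 2.2-fold, adjusted p = 7.6e-10), CG7173 (1.13), ZnT35C (1.09), neo (1.06), CG11825 (1.01) and the microtubule-associated Map205 (0.87) were also higher in the mean of slit and robo, the arrays overlapping for neo. A single group can carry this mean. In slit, robo and comm, CG7173 averaged 13.88, 12.13 and 11.87 and Hsp26 12.62, 11.19 and 10.77, mostly by slit. CG11825 was even in slit and robo (11.55 and 11.49, with 10.52 in comm). Higher in comm were Uhg1 (-1.71 ± 0.13, 3.28-fold, adjusted p = 1.7e-17), the lysosomal mannosidase LManV (-0.98), trx and Ugt37A2 (both -0.97), cathD (-0.93), CHKov1 and Fmo-1 (both -0.89), CG13315 (-0.86), the cytochrome Cyp12d1-d (-0.77) and the cuticle protein Cpr50Cb (-0.77). In total 553 probe sets were called higher and 568 lower, with 13 and 4 changed at least 2-fold. With array SD as covariate 1698 and with array weights 2721 were called.

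Embryos of the slit.robo group had higher heat shock, cuticle and muscle genes than WT. The same lists were called higher in robo. Heat shock genes were higher for 5 of 7 (median 0.75, adjusted p = 1.1e-06), with Hsp26 at 2.8 ± 0.14 (6.98-fold, adjusted p = 3.6e-27) and Hsp68 at 2.56 ± 0.17 (5.91-fold). Cuticle genes were higher for 18 and lower for 3 (median 0.25, adjusted p = 4.1e-07, and 18 and 3 adjusted over the list alone), with Lcp65Af at 1.51. Muscle genes were higher for 14 and lower for 2, with 5 not passing (median 0.35, adjusted p = 0.00031), with the troponin gene up at 1.09. Neuron genes were higher for 11 and lower for 5 (adjusted p = 0.0027), and signalling genes higher for 8 and lower for 0 (adjusted p = 0.0026), with the actin regulator ena at 1.1. The cell cycle list had 13 lower and 2 higher (adjusted p = 0.019, but adjusted p = 0.16 with an estimated correlation). CG11825 (3.55 ± 0.11, 11.7-fold), Cpr67Fa2 (2.99 ± 0.17, 7.95-fold) and CG34166 (2.79) were also among the highest, and Uhg1 (-1.99), ImpL1 (-1.73 ± 0.12, 3.32-fold), cathD (-1.55), CG12920 and CG9184 (both -1.46) the lowest. Against slit alone, the cuticle genes Lcp65Af (1.86 ± 0.1, 3.63-fold, adjusted p = 2.5e-25), Cpr67Fa2 (1.79), CG18649 (1.78), the chitin-binding obst-E (1.73 ± 0.11, 3.31-fold) and Cpr47Eg (1.72) were higher. Against slit, neo (-2.19 ± 0.1, 4.55-fold, adjusted p = 5.7e-29), ImpL1 (-2.05 ± 0.12, 4.13-fold), CG9184 (-1.8), CG7173 (-1.68) and CG14110 (-1.65) were lower. Against robo alone, Hsp26 (1.62 ± 0.15, 3.07-fold, adjusted p = 1.9e-13), the neuronal RNA-binding gene elav (1.55 ± 0.2, 2.92-fold), Hsp68 (1.41), CG34166 (1.33) and Lcp65Af (1.25) were higher, and Elba3 (-0.97), udd (-0.91) and cathD (-0.83) lower. The calls were 2957 higher and 5016 lower against WT, 1412 and 991 against slit, and 2089 and 1918 against robo. The array SD was 1.797 in slit.robo, and with it as covariate 4222 were called against WT and 1820 against robo. Against robo the count was 2130 without robo replicate 2, 1992 without robo replicate 3 and 2560 without slit.robo replicate 3.

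In robo12, heat shock genes were again higher, for 4 of 7 with 0 lower (median 0.36, adjusted p = 4.1e-07, and 4 adjusted over the list alone), with Hsp26 at 1.66 ± 0.15 (3.16-fold), Hsp68 at 1.42 and DnaJ-1 at 1.11. Cell cycle genes were lower for 8 and higher for 0 (adjusted p = 0.00035, and 9 lower adjusted over the list alone), with CycB3 at -1.01. Cuticle genes were higher for 9 and lower for 0 (adjusted p = 6e-04, but adjusted p = 0.097 with an estimated correlation). The list of fat body and midgut genes had 4 lower and 0 higher (adjusted p = 0.045, but adjusted p = 0.39 with an estimated correlation). CG11825 (3.76 ± 0.12, 13.6-fold), CG34166 (2.04) and Drsl5 (2.01 ± 0.11, 4.03-fold) were the highest, and Uhg1 (-1.96), cathD (-1.41), CG17047 (-1.39), ImpL1 (-1.3) and CG18507 (-1.2) the lowest. Against robo, the serpin Spn43Aa (1.82 ± 0.1, 3.52-fold, adjusted p = 1.6e-23), Drsl5 (1.23), the cytochrome Cyp6d5 (1.13), CG3108 (0.89) and the serpin nec (0.71) were higher. Lower against robo were the sulfotransferase St3, the troponin gene up (-0.95 ± 0.12, 1.93-fold, adjusted p = 3e-08), CG18507 and udd (all -0.95), and yellow-h (-0.8). Against robo2, Spn43Aa (2.17 ± 0.1, 4.51-fold, adjusted p = 4.4e-28), Lapsyn (1.57), ImpL1 (1.5 ± 0.13, 2.82-fold), CG3108 (1.33) and CG7173 (1.31) were higher. Lower against robo2 were the immune peptide BomS5 (-1.43 ± 0.09, 2.69-fold), the glycogen primer gene Gyg (-1.31), Cpr67Fa2 (-1.28), cathD (-1.27) and CG13323 (-1.22). The calls were 1188 higher and 1416 lower against WT, 517 and 481 against robo, and 1183 and 1170 against robo2. With only the compared groups in the fit 1071 were called against WT. Against robo the count was 610 without robo replicate 1, 492 without robo replicate 4, 525 without robo12 replicate 1 and 607 without robo12 replicate 4.

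The /WT groups asked what a single dose of each mutation does. In slit/WT, guidance ligands and receptors were higher for 18 and lower for 2 of 25 (median 0.28, adjusted p = 2e-06, and 19 and 2 adjusted over the list alone), and adhesion genes higher for 15 and lower for 0 (median 0.49, adjusted p = 1.6e-07, and 16 adjusted over the list alone), with Con at 1.75 and CadN at 1.53. Fat body and midgut genes were lower for 12 and higher for 1 (median -0.45, adjusted p = 0.0041, but adjusted p = 0.19 with an estimated correlation), and Jon25Biii (-0.97), Jon99Fii (-0.93), Jon25Bii (-0.78) and epsilonTry (-0.78), all digestive proteases, were among the lowest genes. Jon99Fi fell by 1.14 ± 0.3 (2.2-fold, adjusted p = 0.00082), lost with array SD as covariate (-0.59, adjusted p = 0.17), as was the call of Jon99Fii (-0.46, adjusted p = 0.15). With only the compared groups in the fit, Jon99Fi (adjusted p = 0.17), Jon99Fii (adjusted p = 0.16) and Jon25Biii (adjusted p = 0.073) were lost, and the WT arrays had SDs of 1.64, 1.3 and 1.03 in these genes. Egg chamber genes were lower for 14 of 15 (median -0.31, adjusted p = 0.0014, but adjusted p = 0.18 with an estimated correlation). CG11825 (2.45, 5.46-fold), aqz (2.36 ± 0.14, 5.14-fold), the RNA-binding gene bol (1.89 ± 0.16, 3.7-fold), the kinase gene Hipk (1.87) and DCP2 (1.75) were the highest in slit/WT. In robo/WT, heat shock genes were higher for 5 of 7 (median 0.66, adjusted p = 0.00016), the highest genes were CG11825 (3.4, 10.6-fold), DCP2 (1.77), udd (1.4), the splicing regulator Rbfox1 (1.32) and shn (1.29), and the lowest CG13315 (-1.78), CG5171 (-1.12), swa (-0.89), Jon25Biii (-0.88, lost with only the compared groups, adjusted p = 0.13) and CG4666 (-0.88). The robo/WT arrays had GAPDH and actin 3'-to-5' differences of 2.19 and 1.35, each array above every WT array. In comm/WT, heat shock genes were also higher for 5 of 7 (median 0.74, adjusted p = 2.8e-06). Adhesion genes were higher for 14 and lower for 2 in comm/WT (median 0.44, adjusted p = 8.2e-05, but adjusted p = 0.081 with an estimated correlation), and hemocyte genes higher for 13 and lower for 0 (adjusted p = 6e-04, but adjusted p = 0.17 with an estimated correlation). The highest there were CG11825 (3.32 ± 0.12, 9.97-fold), Cpr67Fa2 (2.37), Cht6 (2), DCP2 (1.92) and Hsp68 (1.91 ± 0.18, 3.76-fold), and the lowest CG9184 (-1.37), CG12920 (-1.31), Hr4 (-1.23 ± 0.12, 2.35-fold), neo (-1.19) and the lipid droplet gene Lsd-2 (-1.06). The calls against WT were 3519 higher and 5238 lower in slit/WT, 2875 and 3637 in robo/WT, and 2947 and 4668 in comm/WT, where the GAPDH 3'-to-5' difference was 2.28 and that of actin 1.63. These comm/WT means were carried by replicates 1 and 2, with GAPDH at 2.8 and 2.75 and actin at 2.05 and 2.12. Replicates 3 and 4 had GAPDH at 1.81 and 1.78 and actin at 1.23 and 1.14. With array SD as covariate 4773 were called in slit/WT, and without arrays that stand apart 4169 in comm/WT. There, the calls in comm/WT changed at least 2-fold went from 159 to 73.

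Between the doses, slit exceeded slit/WT in ZnT35C (1.39 ± 0.09, 2.62-fold, adjusted p = 6.2e-20), Hsp26 (1.19 ± 0.16, 2.28-fold), CG11825 (1.1), Hsp68 (1) and pst (0.98), and lay below it in Uhg1 (-1.73), elav (-1.49 ± 0.21, 2.81-fold, adjusted p = 9.3e-08), CG7465 (-1.31), bol (-1.28) and Hipk (-1.23). In robo against robo/WT, CG15731 (1.05), CG15615 (0.99), Cpr67Fa2 (0.96), CG14327 (0.95) and CG34276 (0.91) were higher, and ImpL1 (-1.9 ± 0.13, 3.74-fold, adjusted p = 1.3e-19), CG42331 (-1.45), CG9184 (-1.43), CG6026 (-1.4) and Uhg1 (-1.36) lower. In comm against comm/WT, the ecdysone-response receptor Hr4 (1.36 ± 0.12, 2.56-fold, adjusted p = 8.8e-14), CG15731 (0.89), the neuropeptide receptor TrissinR and the chitin deacetylase Cda4 (both 0.83) and the titin-like sls (0.79 ± 0.09, its other probe sets not called) were higher. Lower in comm were Drsl5 (-1.52 ± 0.11, 2.87-fold, adjusted p = 1e-17), Pabp2 (-1.09), Hsp68 (-1.05), Uhg1 (-1.03) and Jon99Fi (-0.98), the last lost without comm/WT replicate 1 (adjusted p = 0.058) or 2 (adjusted p = 0.065). The calls were 1925 higher and 1754 lower for slit, 1682 and 2386 for robo, and 1329 and 1719 for comm. Without robo/WT replicate 4 the robo count was 2654, and the comm count was 2003 without comm/WT replicate 1 and 1926 without comm/WT replicate 2. With the WT arrays split, the direction was shared by 90.7% of 4991 probe sets for slit, where simulated unchanged groups gave a median of 51.3% and groups without slit in their names a median of 77.6% and up to 84.4%. It was shared by 74.3% of 2774 for robo (simulated 49.5%, groups other than slit.robo and robo12 68.2% and up to 86.3%) and by 85.6% of 4075 for comm (simulated 49.8%, groups without comm in their names 73.6% and up to 83.5%). Splitting the WT arrays the other way gave 81.1% for robo and 90.9% for comm.

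UC and UC2x, the groups with raised comm, differed widely from each other. In UC, cuticle genes were higher for 16 and lower for 3 of 25 (median 0.28, adjusted p = 1.1e-06, and 18 and 3 adjusted over the list alone), with the pigmentation gene y at 0.59 and Lcp65Ac at 0.79. Cell cycle genes in UC were lower for 11 and higher for 0 (median -0.14, adjusted p = 0.0026, but adjusted p = 0.066 with an estimated correlation). The genes ImpL1 (-3.25 ± 0.12, 9.49-fold, adjusted p = 6.5e-34), flz (-2.48 ± 0.12, 5.57-fold), CG7173 (-2.12), CG4702 (-2.11) and CG3108 (-2.1) were the lowest in UC, and ImpE2 fell by 1.22. The netrin receptor gene fra fell in UC by 0.87 ± 0.13 (1.83-fold, adjusted p = 2.7e-07), and UC2x exceeded UC in fra by 0.98 (1.98-fold, adjusted p = 4.8e-09). In UC2x, fat body and midgut genes were higher for 10 and lower for 2 of 14 (median 0.82, adjusted p = 3.5e-07, and 10 and 2 adjusted over the list alone), with the proteases Jon25Bii at 1.95, Jon65Aiv at 1.94 and Jon25Bi at 1.45. Other proteases of this family, which digest food in the larval midgut, were the highest genes of UC2x: Jon99Fi (5.17 ± 0.28, 36-fold, adjusted p = 1.8e-25), Jon99Fii (3.51 ± 0.21, 11.4-fold) and Jon25Biii (3.2 ± 0.18, 9.18-fold), then CG7465 (2.76) and CG12310 (2.61). The WT arrays had SDs of 1.64 in Jon99Fi, 1.3 in Jon99Fii and 1.03 in Jon25Biii. The SE and p-values, from a spread common to all groups, therefore overstate the precision for these proteases. Jon99Fi also rose in UC (2.74 ± 0.3, 6.68-fold), with arrays that overlapped WT, as did those of Jon25Biii (1.87). Guidance genes were higher for 12 and lower for 1 in UC2x (adjusted p = 0.0034), and egg chamber genes lower for 12 of 15 (median -0.28, adjusted p = 0.0011, but adjusted p = 0.17 with an estimated correlation). The lowest in UC2x were CG18814 (-1.09), Cpr67Fa2 (-1.07, arrays overlapping) and CG13813 (-1.01). Between them, ImpL1 (3.37 ± 0.12, 10.3-fold, adjusted p = 3.4e-35), flz (2.84, 7.14-fold), CG14107 (2.72), CG7173 (2.7) and CG3108 (2.64) were higher in UC2x, and Cpr67Fa2 (-1.53), CG1441 (-1.41), EAChm (-1.39), CG15023 (-1.33) and CG17290 (-1.32) lower. The calls were 1733 higher and 2144 lower in UC, 3380 and 4849 in UC2x, and 4259 and 5398 between them. The array SD was 1.703 in UC and 1.797 in UC2x, and with it as covariate 3840 were called in UC2x and 4378 between them. With only the compared groups in the fit 1646 were called in UC.

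In UNC5, beside unc-5 itself, cuticle genes were higher for 14 and lower for 2 of 25 (adjusted p = 3.5e-05), and muscle genes higher for 12 and lower for 4 (adjusted p = 0.002, but adjusted p = 0.079 with an estimated correlation), with the troponin gene up at 1.06. Gad1 rose by 0.93. Jon99Fi (2.8 ± 0.28, 6.96-fold, arrays overlapping), bol (2 ± 0.15, 4-fold), aqz (1.99), CG34166 (1.96) and Drsl5 (1.89 ± 0.1, 3.7-fold) were the highest. Uhg1 (-1.77), ImpL1 (-1.14), neo (-0.97), CG14960 (-0.96) and the synaptotagmin gene Syt7 (-0.95) were the lowest. The calls were 2931 higher and 4645 lower. The array SD was 1.797, and with it as covariate 3120 were called and 4 of 9 called lists kept.

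In UR, UR2, URyf and URyf.mef the gene lists were tested against WT alone, and single genes also between these groups. In UR, guidance genes were higher for 9 and lower for 2 of 25 (adjusted p = 0.0012), neuron genes higher for 8 and lower for 1 (adjusted p = 0.0019), and cuticle genes higher for 11 and lower for 0 (adjusted p = 1.7e-06), with Cpr67Fa2 at 2.62 ± 0.18 (6.15-fold) and Lcp65Af at 1.33. The next highest in UR were Jon99Fi (2.43, arrays overlapping), CG34166 (1.98), bol (1.83) and Drsl5 (1.75), and the lowest Uhg1 (-1.95) and CG6118 (-1.21). In UR2, cell cycle genes were higher for 9 and lower for 2 of 21 (adjusted p = 0.0014, and 10 and 3 adjusted over the list alone), with CycB3 at 1.41, CycB at 0.95 and the mitotic-exit gene fzy at 0.85. Drsl5 (2.79 ± 0.11, 6.93-fold, adjusted p = 1.1e-33), smg, a maternal RNA-binding repressor (1.94 ± 0.11, 3.85-fold), bol (1.94), Cpr67Fa2 (1.71) and Cht6 (1.69) were the highest in UR2, and Uhg1 (-1.88) and the maltase Mal-B1 (-1.18) the lowest. Against UR, UR2 was lower in robo1 (-1.17, 2.25-fold, adjusted p = 5.2e-21), Jon99Fi (-2.63 ± 0.31, 6.2-fold) and Muc55B (-1.31), and higher in the odorant-binding protein gene Obp99a (1.14 ± 0.09, 2.2-fold, adjusted p = 3.7e-17). In URyf, cuticle genes were higher for 7 and lower for 0 (adjusted p = 0.00031, but adjusted p = 0.081 with an estimated correlation), and after robo1 the highest were Drsl5 (2.25 ± 0.1, 4.74-fold) and CG11825 (2.2, 4.59-fold). The lowest in URyf were Mal-B1 (-1.03), Syt7 (-0.91) and CG13315 (-0.86). Against UR, URyf was higher in CG11825 (2.18), Uhg1 (1.28) and robo1 (1.05, 2.07-fold, adjusted p = 5.9e-20), and lower in Cpr67Fa2 (-1.47), Jon99Fi (-1.38) and the glutamate receptor gene Nmda1 (-1.16 ± 0.18). In URyf.mef, cell cycle genes were higher for 11 and lower for 6 (median 0.15, adjusted p = 0.0078, but adjusted p = 0.1 with an estimated correlation), with CycB3 at 1.88 and CycB at 1.32. Fat body and midgut genes were higher there for 9 and lower for 2 (adjusted p = 0.0022, but adjusted p = 0.16 with an estimated correlation). CG11825 (4.73 ± 0.11, 26.5-fold, adjusted p = 4.8e-47), Jon99Fi (3.86, 14.5-fold), Drsl5 (3.49, 11.2-fold) and robo1 (3.2) were the highest, and CG5171 (-1.74) and Mal-B1 (-1.45) the lowest. Against URyf, URyf.mef was higher in Jon99Fi (2.81, 7-fold), CG11825 (2.53), CG12868 (2.17), smg (2.01 ± 0.1, 4.04-fold) and robo1 (0.83, 1.77-fold, adjusted p = 5.5e-17), and lower in CG5171 (-1.31), the purine-synthesis gene Prat2 (-0.75) and Cyp309a2 (-0.73).

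The calls in these groups were 2009 higher and 2630 lower in UR, 2316 and 2952 in UR2, 666 and 700 in URyf, and 3396 and 5686 in URyf.mef against WT. Between groups they were 407 and 409 for UR2 against UR, 1894 and 2030 for URyf against UR, and 3732 and 5429 for URyf.mef against URyf. The URyf arrays had the widest range of array SD within a group (1.71 ± 0.057), and the count against WT was 2233 without WT replicate 1, 89 with only these groups in the fit and 2428 without arrays that stand apart. In URyf.mef the actin 3'-to-5' difference was 1.22, each array above every WT array. The array SD there was 1.805, and with it as covariate 3349 were called against WT and 2269 against URyf.

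In FRM, where robo1 was raised, cuticle genes were higher for 13 and lower for 1 of 25 (median 0.18, adjusted p = 4.1e-07), with Cpr67Fa2 at 2.57 ± 0.18 (5.94-fold), Lcp65Af at 1.99 ± 0.1 (3.96-fold) and Lcp65Ac at 1.46. Neuron genes were higher for 9 and lower for 5 (adjusted p = 0.0092), with Gad1 at 0.93, and guidance genes higher for 8 and lower for 1 (adjusted p = 0.0074). The cyclins CycB3 (1.72) and CycB (1.13) rose, as did smg (2.24 ± 0.11, 4.73-fold, adjusted p = 1.4e-27), CG34166 (1.88), the Toll receptor gene Tl (1.01) and Jon99Fi (1.92, arrays overlapping). Mal-B1 (-1.03), CG7763 (-0.99), Uhg1 (-0.94, arrays overlapping), BomS2 (-0.87) and CG18814 (-0.86) were the lowest. The calls were 2427 higher and 3272 lower, and 3503 with only the compared groups in the fit. The array SD was 1.765, and 3 of 8 called lists were kept with it as covariate. Without dim probe sets 2 of these 8 were kept.

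Over all groups, 137 of the 289 list tests were called, 120 higher and 17 lower, and 48 with an estimated correlation, all 48 in the same direction. In the called tests, 1002 members were higher and 339 lower, and 1035 and 367 adjusted over the list alone. Heat shock genes rose in 9 groups, all named for comm, robo or slit, and 8 of these held with an estimated correlation. Cuticle genes rose in 13 groups (6 with an estimated correlation), adhesion genes in 12 (2), guidance ligands and receptors in 12 (6), midline genes in 12 (5), muscle genes in 12 (2), neuron genes in 11 (8) and guidance signalling genes in 11 (4). Cell cycle genes fell in 6 groups (3) and rose in 2 (1), and ecdysone genes rose in 2 (2). Glia genes rose in 8, hemocyte and basement membrane genes in 10, and neural precursor genes in 1, slit/WT (8 higher, 5 lower, adjusted p = 0.036), and of all these 0 held with an estimated correlation, with adjusted p = 0.2 with an estimated correlation for neural precursors. Antimicrobial peptides rose in 2 groups, UC and URyf, and fell in comm, and egg chamber genes fell in 7, and of these also 0 held. Fat body and midgut genes rose in 3 groups (1) and fell in 3 (0). Early embryo patterning genes were called in 0 groups by camera, and in 2, UNC5 and URyf.mef, at an unadjusted p under 0.05, with medians from -0.18 to -0.01. With array SD as covariate 86 of the 137 calls were kept, including 9 of 9 for heat shock, 12 of 13 for cuticle, 8 of 8 for cell cycle, 4 of 12 for adhesion and 1 of 10 for hemocytes. Without dim probe sets 76 of the 137 were kept, with 1 of 12 for guidance ligands and receptors, 4 of 12 for midline and 0 of 8 for glia.

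**Figure D4:**
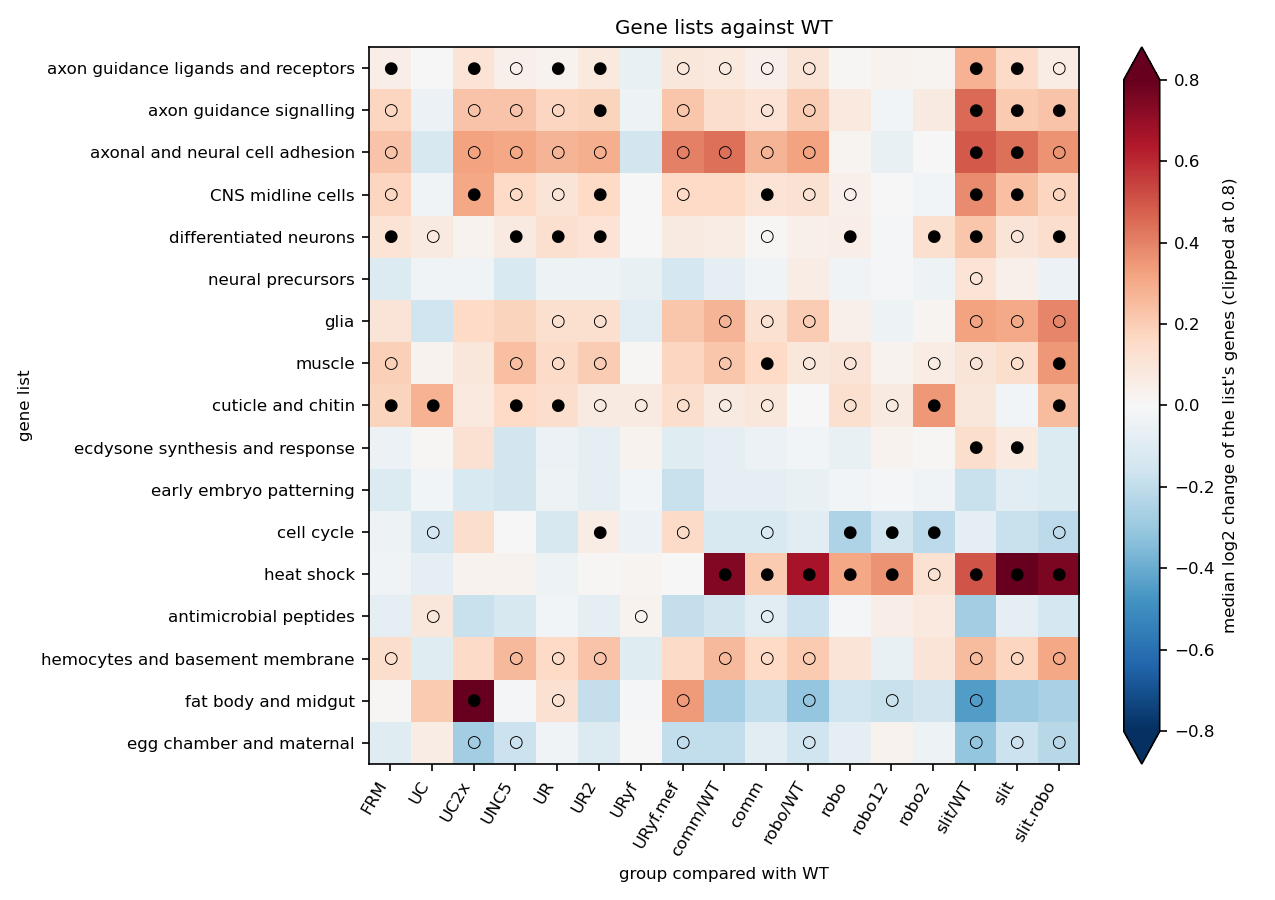
Median log2 change against WT (colour) of each gene list (y axis) in each group (x axis), with circles where the list was called and filled circles where the call held with an estimated correlation. The heat shock list reaches a median of 0.8 in slit, and the fat body and midgut list 0.82 in UC2x.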

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

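The tests of explanations in this part were chosen after the results were seen. The lists for axon guidance ligands and receptors, adhesion, midline cells, neurons and muscle were called higher than WT in 59 of 85 pairs of list and group. With array SD as covariate 37 calls stayed, which argues against the narrower range of the WT arrays as their whole cause. For the other 22, the median of the list means went from 0.23 (IQR 0.08) to 0.12 (IQR 0.09), so these calls ended with a smaller change, and for them array range and genotype cannot be told apart. Against the mean of the other groups in place of WT 10 calls stayed, which decides nothing, because a rise that most groups share shrinks against their own mean whatever its cause. A property of the WT arrays that no other group shares and an effect of the genotypes cannot be told apart, since all comparisons use the same WT arrays.

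ImpL1, flz, CG7173, CG14960 and CG9184 were lower than WT in UC, robo2, robo, slit.robo and comm, in 25 of 25 pairs of gene and group. All 25 remained lower with array SD as covariate, which argues against array range. The fall was not limited to these groups. All 5 genes were also called lower in UNC5, robo12, comm/WT, URyf and UR2, from -0.31 (flz in UR2) to -1.37 (CG9184 in comm/WT). The 5 genes had a median change of 0.32 in slit, with a range of 0.16 to 0.42, and 0.2 in UC2x. The medians did not stay above 0 with array SD as covariate, at 0 in slit (range -0.17 to 0.28) and -0.14 in UC2x. In slit neither fit gave a fall like that in the 5 groups. By its name slit lost the repellent, which would go against loss of midline repulsion as a common cause. The sli values could not check that loss, and slit.robo, by its name also a slit mutant, had the fall (ImpL1 -1.73). Loss of midline repulsion is therefore left undecided. A difference in embryo age at collection is a candidate explanation: over 18 group means, the 5 genes correlated with the cuticle list at Pearson -0.653 (permutation p = 0.0036, adjusted p = 0.007) and Spearman -0.635 (permutation p = 0.0058, adjusted p = 0.0058), and at -0.759 (permutation p = 0.00061) without the groups slit.robo and FRM. ImpL1 alone gave -0.613 (permutation p = 0.007) and -0.639 (permutation p = 0.0053), and -0.74 (permutation p = 0.00086) without those groups, with 2 relations computed in all. The 5 genes were picked for their falls, and the cuticle list had already been called higher in UC, robo2, robo and slit.robo. The permutation p-values ignore that choice, so the correlation does not test embryo age. An effect of genotype on epidermal maturation would give the same correlation and stays open, untested.

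CG11825 was higher than WT in each group named for comm, robo or slit, and in URyf and URyf.mef, by 2.2 or more, and by less in UR2 (0.93), UC2x (0.63), UNC5 (0.52), UC (0.48) and FRM (0.42), while UR had 0.02, which did not pass. Linkage to the slit or robo mutation as the cause in all these groups is argued against by the change of 2.51 in comm, a gene on another chromosome. Whether linkage adds to the rise in the groups named for slit or robo cannot be told from that value. The dose of the mutated gene is argued against in comm, which lay at -0.8 against comm/WT (adjusted p = 1.2e-06), goes with the value in slit, which lay at 1.1 against slit/WT, and is undecided in robo, at 0.09. A stock variant under the probe set could not be tested, because the gene has 1 probe set, so a variant and a change in transcript level cannot be told apart. Apart from the dose of the mutated gene, no biological explanation was tested for CG11825.

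Values far from the rest of their group were found in 12 of 180 combinations of group and measure, where chance gives about 1 in 20. The comm transcript was lowest in robo12 replicate 1 (11.69), and comm2 in UR2 replicate 4 (10.99). The fra transcript was lowest in WT replicate 1 (10.09) and in UC replicate 1 (9.64). NetB was lowest in URyf replicate 1 (9.85), robo12 replicate 2 (10.89) and slit/WT replicate 2 (11.33). The array SD was lowest in URyf.mef replicate 5 (1.78) and slit/WT replicate 2 (1.78), and highest in comm/WT replicate 4 (1.778) and robo/WT replicate 4 (1.789). The GAPDH 3'-to-5' difference was lowest in UR replicate 4 (1.63).

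Control probe sets that no comparison uses differed from WT. The group mean of the GAPDH 3'-to-5' difference lay at 1.92 in comm and 2.19 in robo/WT, where the highest WT array had 1.86. For actin, the means were 1.22 in URyf.mef, 1.46 in comm, 1.63 in comm/WT, 1.24 in robo and 1.35 in robo/WT, where the highest WT array had 1.06. In these 7 means every array lay above every WT array.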

How the results depend on the processing

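Array SD as covariate and the fit without arrays that stand apart were chosen after the data were seen, and the other settings before. Of 540 results for named genes, the side of the threshold, and the direction of results past it, held for 518 after quantile normalization, 538 with a replicate block, 519 with array weights, 504 with array SD as covariate, 511 without arrays that stand apart and 506 with only the compared groups. They held for 479 of 483 without dim probe sets, for 271 of 327 against the mean of the other groups, and for 4820 of 4939 repeats that left out an array. Results that passed in neither fit counted as held whatever their direction. The replicate numbers do not pair the arrays: 22 of 78 arrays correlated best with arrays of their own number, and with the replicate block the lower robo1 in robo had an adjusted p = 0.065. No scaling moved the median of all genes by over 0.1. Where not stated, the cause was not tested.

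Without dim probe sets, fewer genes were tested and fewer called: FRM 3393, UC2x 5247, UNC5 4832, UR 2995, UR2 3118, URyf.mef 5419, comm/WT 4986, slit/WT 5383, slit 3535 and slit.robo 4911 against WT, UC2x against UC 6235, URyf against UR 2363, URyf.mef against URyf 5471, the F test 8251, and 77 list tests. The share called higher then went from 41.1 to 53.1% in UC2x, 38.7 to 51.3% in UNC5, 44 to 55% in UR2, 37.4 to 48.7% in URyf.mef, 40.2 to 51.1% in slit/WT, 39.6 to 51.1% in slit, 37.1 to 48.4% in slit.robo, 52.1 to 63.2% in slit.robo against robo, 44.1 to 55.5% in UC2x against UC, 48.3 to 35% in URyf against UR and 40.7 to 53.2% in URyf.mef against URyf.

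With only the compared groups in the fit, the spread was set by their own arrays. The median SD of replicates was 0.134 in WT and 0.153 in URyf, but 0.067 in UR and 0.062 in UR2. The fit over all groups used a common spread, so its SE can be too small where replicates vary more, as in WT and URyf. With only the compared groups the calls were FRM 3503, UC 1646, UR 2613, UR2 3211, URyf 89, comm/WT 4597, comm 1715, robo/WT 3822, robo 709, robo12 1071, robo2 1944, slit 1970, slit.robo against robo 2528, UR2 against UR 2294 and URyf against UR 1219. With array weights they were robo against robo/WT 6441, slit.robo against robo 7688, robo12 against robo 1500, robo12 against robo2 3647, UR2 against UR 2628, and slit and robo against comm 2721. With array SD as covariate they were UC2x 3840, UNC5 3120, URyf 2162, URyf.mef 3349, slit/WT 4773, slit 3154, slit.robo 4222, slit.robo against robo 1820, UC2x against UC 4378, URyf.mef against URyf 2269 (56.1% higher, from 40.7%), and slit and robo against comm 1698. Without arrays that stand apart they were URyf 2428, comm/WT 4169 (49% higher, from 38.7%), comm against comm/WT 1512, slit.robo against robo 6505 and UR2 against UR 1244. Against the mean of the other groups they were FRM 2655, UC 9096, UNC5 3343, UR 1565, UR2 2025, URyf 6707, comm 1601, robo12 6535, slit 3030 and slit.robo 4531. Splitting the WT arrays the other way gave a shared direction of 81.1% for robo and 90.9% for comm.

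Of 17 comparisons per list, the calls after quantile normalization were 5 for hemocytes, 6 for muscle and 0 for neural precursors. Without dim probe sets they were 1 for antimicrobial peptides, guidance ligands and receptors, and ecdysone, 5 for cell cycle, 4 for midline, 2 for hemocytes, and 0 for glia and neural precursors. With array weights, neural precursors had 2. With array SD as covariate there were 5 for antimicrobial peptides and midline, 7 for signalling, 4 for adhesion, 0 for egg chamber, 2 for glia, 1 for hemocytes, 6 for muscle and 3 for neural precursors. Without arrays that stand apart there were 4 for egg chamber, 5 for glia and 2 for neural precursors. Against the mean of the other groups there were 8 for antimicrobial peptides and cuticle, 4 for guidance ligands and receptors and for muscle, 5 for signalling, 2 for midline and early patterning, 1 for neurons, 11 for fat body and midgut, and 14 for heat shock. With an estimated correlation, 48 calls in all, there were 0 for antimicrobial peptides, egg chamber, glia, hemocytes and neural precursors, 6 for guidance ligands and receptors and for cuticle, 4 for signalling and cell cycle, 2 for adhesion and muscle, 5 for midline, and 1 for fat body and midgut.

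Leaving out each array in turn gave 1070 to 2233 calls in URyf (2233 without WT replicate 1), 2454 to 4418 in comm (2454 without WT replicate 1), 1926 to 3466 for comm against comm/WT (2003 and 1926 without comm/WT replicates 1 and 2), 2654 to 4997 for robo against robo/WT (2654 without robo/WT replicate 4), 1992 to 5275 for slit.robo against robo (2130 and 1992 without robo replicates 2 and 3, 2560 without slit.robo replicate 3) and 492 to 1078 for robo12 against robo (610 and 492 without robo replicates 1 and 4, 525 and 607 without robo12 replicates 1 and 4). For lists it gave 4 to 8 for egg chamber (4 without WT replicate 1 or 5), 5 to 11 for fat body and midgut (11 without WT replicate 3), 6 to 11 for hemocytes (6 without WT replicate 1), 0 to 1 for early patterning (1 without URyf.mef replicate 5 or WT replicate 2 or 3) and 0 to 2 for neural precursors (0 without WT replicate 2 or 4, 2 without WT replicate 1 or 5 or robo/WT replicate 4).

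Among results that passed in either fit, directions turned after quantile normalization for comm in slit/WT (0) and slit.robo (-0.13), and with array SD as covariate for fra in URyf.mef (-0.14). Against the mean of the other groups they turned for Uhg1 in FRM (0.16), aqz in URyf (-0.2), robo (-0.18) and slit (-0.1), CG12920 in URyf (0.08), unc-5 in UC2x (-0.12), robo1 in UC and UC2x (both -0.4), UNC5 (-0.41), UR2 (-0.3), comm (-0.42), robo2 (-0.44), slit/WT (-0.16) and slit (-0.45), and NetB in UC (-0.5), UC2x (-0.05), URyf (-0.48), comm/WT (-0.18), robo/WT (-0.02) and robo12 (-0.06). Groups with raised robo1 enter that mean.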

Other observations

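Tests of hypotheses in this part were chosen after the result was seen. The maternal RNA-binding repressor smg fell in all 9 groups named for comm, robo or slit, from -0.52 in slit/WT to -1.07 in robo12, and rose in FRM (2.24 ± 0.11), UR2 (1.94 ± 0.11), URyf.mef (2.3), UR (1.17), UNC5 (0.94) and UC2x (0.59), with 0.23 in UC and 0.29 in URyf that did not pass. The cyclins CycB3 and CycB rose in FRM by 1.72 and 1.13, in UR2 by 1.41 and 0.95, and in URyf.mef by 1.88 and 1.32, and in robo they had -1.1 and -0.61. The midgut protease Jon99Fi rose in FRM (1.92), URyf (1.05), UR (2.43), UC (2.74), UNC5 (2.8), URyf.mef (3.86) and UC2x (5.17 ± 0.28), and had -0.2 in UR2, which did not pass. In the groups named for comm, robo or slit its changes lay between -1.14 and -0.09, but its WT arrays had an SD of 1.64. Without arrays that stand apart the change in slit was -0.25 (adjusted p = 0.064), and with array SD as covariate the calls in slit and slit/WT were lost (adjusted p = 0.18 and 0.17). These genes were singled out after their values were seen, and the difference between the 2 sets of groups was not tested.

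Drsl5, a drosomycin-like peptide, fell in comm (-1.84) and comm/WT (-0.32) and rose in the 15 other groups. The ecdysone-inducible genes ImpE1 and ImpE2 fell with ImpL1 in UC (-0.89 and -1.22). The translational repressor brat, which limits neural precursor growth, rose in all 17 groups, from 0.67 to 1.47, and the neuronal sodium pump subunit nrv3 from 0.31 to 1.27. The glutamine synthetase gene Gs2, active in glia, rose by 1.45 in URyf.mef and 0.71 in slit.

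A hypothesis was that groups that share a mutation share directions of change more than unrelated groups do. Groups were ranked by shared direction with the WT arrays split, and other groups with the same gene in their names were left out of the ranking. In this order slit/WT ranked 1 for slit and comm/WT ranked 1 for comm, also with array SD as covariate. For comm the margin was narrow, with 85.6% in comm/WT against 83.5% in slit.robo. With array SD as covariate it was 76.6% in comm/WT against 76.2% in robo. In robo, robo/WT ranked 3 with 74.3%, below comm with 86.3%, and slit.robo and robo12, which are by their names also robo mutants, shared 82.9% and 71%, so this was left undecided. UC2x ranked 14 of 16 for UC, with 46.9% of 2927 probe sets against a median of 66.8% in the unrelated groups. It shared 66.7% of 3576 and ranked 13 with array SD as covariate, against a median of 79.9%. UC2x therefore did not share directions with UC more than unrelated groups did, which leaves open whether part of the response was common. Jon99Fi and Jon25Biii rose in both (2.74 and 5.17, 1.87 and 3.2), with UC arrays that overlapped WT. That rise was not particular to them. Jon99Fi averaged 10.81 in UNC5 and 11.87 in URyf.mef, but 7.81 in UR2, against 8.01 in WT. Jon25Biii averaged 12.54 in URyf.mef and 10.46 in UR2, against 10.13 in WT.

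Another hypothesis was that sequence linked to a mutation changes the neighbours of the mutated gene. Of the 60 nearest measured genes, 2 (3.33%) changed by at least 0.5 in slit, against 3.86% of other genes (Fisher's exact p = 1, adjusted p = 1), 3 (5%) in robo against 3.32% (exact p = 0.45, adjusted p = 0.68) and 4 (6.67%) in comm against 3.91% (exact p = 0.3, adjusted p = 0.68). These 3 tests leave the hypothesis undecided.

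Other splits of the same arrays into groups of the same sizes were fitted, all 35 for groups of 4 and 4 and 100 drawn at random for the rest. Fewer than 5 in 100 splits, the real one included, called as many for these counts against WT, each with its highest other split: FRM 5699 (1 of 100 as large, other 5495), UC 3877 (3, 5468), UC2x 8229 (1, 6875), UNC5 7576 (1, 5130), UR 4639 (1, 4340), UR2 5268 (2, 5448), URyf.mef 9082 (1, 7706), comm/WT 7615 (1, 7368), comm 3829 (2, 3891), robo/WT 6512 (1, 6505), robo12 2604 (2, 3096), robo2 3578 (1, 3255), slit/WT 8757 (1, 8711), slit 5586 (1, 5297) and slit.robo 7973 (1, 7346). Chance cannot be excluded for robo, 2323 (5 of 100, other 4202), nor for URyf, 1366 (22 of 100, other 6065), where a split called several times the real count and so points to a structure of the arrays other than the groups. Splits also called more than the real one in UC, UR2, comm and robo12. With reshuffled deviations and no group effect, slit/WT had calls in 9 of 100 draws, up to 3927, and robo12 in 5, up to 3160. The replicates may be technical, and then no split of these arrays can exclude chance differences between embryo collections.

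Between related groups, fewer than 5 in 100 of the splits called as many for slit against slit/WT 3679 (1 of 35, other 420), robo against robo/WT 4068 (1 of 35, 2962), comm against comm/WT 3048 (1 of 35, 736), slit.robo against slit 2403 (2 of 100, 2658), slit.robo against robo 4007 (2 of 100, 5706), robo12 against robo 998 (1 of 35, 53), robo12 against robo2 2353 (1 of 35, 101), UC2x against UC 9657 (1 of 100, 8815), UR2 against UR 816 (1 of 35, 5), URyf against UR 3924 (1 of 100, 3755), URyf.mef against URyf 9161 (1 of 100, 8780) and slit and robo against comm 1121 (4 of 100, 1872). The same held for the F test, 13578 (1 of 100, 37), and the list tests, 137 (2 of 100, 152). Other splits called more than the real one for slit.robo against slit, slit.robo against robo, slit and robo against comm, and the list tests. With reshuffled deviations and no group effect, UR2 against UR had calls in 4 of 100 draws, up to 3485. The list tests then had a median of 7 calls and up to 82. Here too, chance differences between embryo collections are not excluded.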
